A study of Mus musculus with 18 samples.

How the data were processed

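Poly(A) RNA of 18 mouse libraries was sequenced by the authors on an Illumina HiSeq instrument with paired reads of 150 bases, from 10 µg of total RNA each. Per the labels, 10 libraries came from distal colon in DSS colitis and 8 from colorectal tumours of the azoxymethane and DSS model. The submitters' notes name Trim Galore 0.6.4 for trimming, HISAT2 2.0.5 for alignment and featureCounts 2.0.0 for counting. The genome build is not given in the sources used here. Of 54532 gene identifiers in the tables, 54409 were found in GENCODE M21 (GRCm38) and 53499 had identical coordinates there.

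The deposited tables, 3 in number, hold for each library the authors' counts per gene, which are whole numbers with no scaling. They also hold the authors' FPKM values, whose denominators were 0.899 to 1.08 times the library totals. The deposited tables further give, per comparison, the authors' signal, which is a group mean of scaled counts, with the authors' log2 fold change and the authors' p-value and adjusted p-value. The tool behind these comparisons is not stated. The counts were used here for every test, and the authors' deposited table values served for a check of the calls alone. The colitis libraries share 1 table, and the tumour libraries are in 1 table per line, joined by gene identifier.

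Library totals ran from 16621611 to 23776174 counts. Mitochondrial genes took 2.01 to 3.56% of counts, and the 10 most abundant genes 4.78 to 6.86%. No 2 libraries of a group were copies of each other, with a chi-square per gene of 6.19 to 95.5 between libraries of 1 group over genes with at least 50 counts. A count of 0 was read as up to 3 counts.

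Groups were taken from the labels. Gene tests used edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter on group, a group-means model over all libraries of the tissue and the robust quasi-likelihood F test. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Each KO group was tested against the WT group of its line, and contrasts of contrasts tested whether effects differed between lines or tissues. The libraries carry no batch labels. Gene lists, 35 in number, covered pathways and cell types and were tested with camera in limma 3.58.1 at a preset correlation of 0.01 where at least 3 members were tested, with p adjusted over the lists. The lists held 663 members together with 1 further list of sex-linked genes used as a check, and 1 symbol had no gene in the tables. Lists, tests, the rule for named genes and the alternatives except 2 were chosen before the data were examined.

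Genes named in the text were those that a fixed rule gave. It took Il1f5 and Il1f9 always. Of called genes with mean log2 CPM (counts scaled to depth) of at least 1 and no overlap between KO and WT libraries, predicted genes and immunoglobulin or T cell receptor segments left out, it took the 8 with the largest rise and the 8 with the largest fall. It took up to 4 members with the smallest p of each called list, and 2 members of 7 central lists whether or not they passed. For differences between effects and between WT groups it took the 5 genes with the smallest p. Other genes were named beside counts of 5 or fewer members, or as further called members of a list, after their values were seen.

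Alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter on low counts, the replicate number as a block, an absolute log2 fold change of at least 1, an estimated correlation in camera, fits of the 2 groups compared or of the 4 groups of a line, and each library left out in turn. Where this left 1 library in a group, its spread was assumed to be that of the other groups. An adjusted p under 0.10 and the IL-36 axis list without the targeted genes were added as alternatives after seeing the data. Numbers were gathered with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 and drawn with matplotlib 3.10.9.

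The pipeline was tested on simulated data in 5 draws with 200 changed genes each, of which 4 draws were added after the first was seen. At 4-fold it recovered 94.4% of changed genes in the colitis Il1f5 design, 88.8% in colitis Il1f9, 79% in tumour Il1f5 and 78.8% in tumour Il1f9. At 2-fold it recovered 69.6%, 63.2%, 31% and 24%. Calls on unchanged genes made up 5.96%, 5.12%, 11.4% and 9.19% of all calls, so that the share lay above the nominal 5% in every design. The shifted list was called in 5 of 5 draws of each design, and 1, 4, 1 and 0 of 170 other lists were called. The simulated genes were drawn independently of each other. The draws therefore cannot show how often correlated genes lead to false list calls in the real data.

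Against the authors' deposited table, 2262 genes higher and 1833 lower were called by both in colitis Il1f5, of 2544 and 2136 called by the authors. In colitis Il1f9 the shared calls were 1505 and 1548 of 2125 and 2072. The authors' means there were above 0 for 762 genes in WT and 1060 in KO that have 0 counts in both deposited libraries, so their comparison drew on further data, and its counts and r do not compare the same libraries. The other 6 groups had 0 such genes. In tumours the authors called 1450 higher and 804 lower for Il1f5 and 27 and 43 for Il1f9, which include the 5 and 3 genes called here. Across genes, the log2 fold changes of both sources had r of 0.9997, 0.956, 0.9998 and 0.997 in the order colitis Il1f5, colitis Il1f9, tumour Il1f5, tumour Il1f9. No library was left out. Isoforms and exons were not examined, since the tables hold gene totals.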

Results

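Bulk RNA sequencing was measured in 18 libraries from C57BL/6 mice. Colitis was induced with dextran sulfate sodium (DSS), a detergent-like polymer that injures the colon epithelium, given at 2.5% for 5 days and followed by 2 days of water. The colitis libraries came from a 0.5 cm piece of distal colon and the tumour libraries from colorectal tumours induced with azoxymethane and DSS. Each tissue held 4 groups, namely knockout (KO) and wild-type (WT) mice of an Il1f5 line and of an Il1f9 line. Il1f5, also called Il36rn, encodes the IL-36 receptor antagonist, and Il1f9, also called Il36g, encodes the agonist IL-36 gamma. The Il1f5 colitis groups had n = 3 and the other 6 groups had n = 2. A count of 0 allows up to 3 counts, and such floors cover counting error only. Expression is given as mean ± SD in CPM, that is counts scaled to library depth, KO first, and log2 fold changes as KO over WT ± standard error with adjusted p from edgeR. Medians of gene lists are of log2 fold changes, and counts for a list alone come from p adjusted over its members. Positions are those of the deposited tables, whose genome build is not given in the sources used here.

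The first question was whether each targeted gene was lost in its own line. Il1f9 (ENSMUSG00000044103, chromosome 2, 24186476 to 24193568) fell in the Il1f9 KO groups, from 8.29 ± 4.90 to 0.281 ± 0.329 CPM in colitis (n = 2 and 2, log2 fold change -4.84 ± 0.80, -7.17 without KO 1 to -3.91 without KO 2, adjusted p = 0.00359). In tumours it fell from 62.8 ± 34.4 to 0.0536 ± 0.0758 (n = 2 and 2, adjusted p = 0.0136), where the KO group held 2 counts against 2404, 1179-fold lower with a 95% counting interval of 326 to 9744. The fitted log2 fold change of -10.10 ± 0.79 ran from -13.44 without KO 1, which leaves a KO library at 0, to -9.15 without KO 2. The call ended when only the 2 groups compared were fitted (adjusted p = 0.479). Il1f5 (ENSMUSG00000026983, chromosome 2, 24276954 to 24283426) was detected only in the libraries labelled Il1f5 KO, so these data show no loss of it. It had 0 counts in every WT library of its line and in all 8 libraries of the Il1f9 line. With 0 counts in WT, no fall could show. The colitis libraries labelled Il1f5 KO held 36 to 45 Il1f5 counts. The tumour libraries labelled Il1f5 KO held 102 to 211 Il1f5 counts. Against a floor of 3 counts over the WT group, the libraries labelled Il1f5 KO were at least 44.8-fold higher in colitis and at least 93.4-fold higher in tumours. The edgeR test called the colitis difference (adjusted p = 0.00107) and did not call the tumour difference (adjusted p = 0.0529). The deposited gene totals do not show which exons the Il1f5 reads lie in, and every Il1f5 direction that follows rests on the labels as given.

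**Figure D1:**
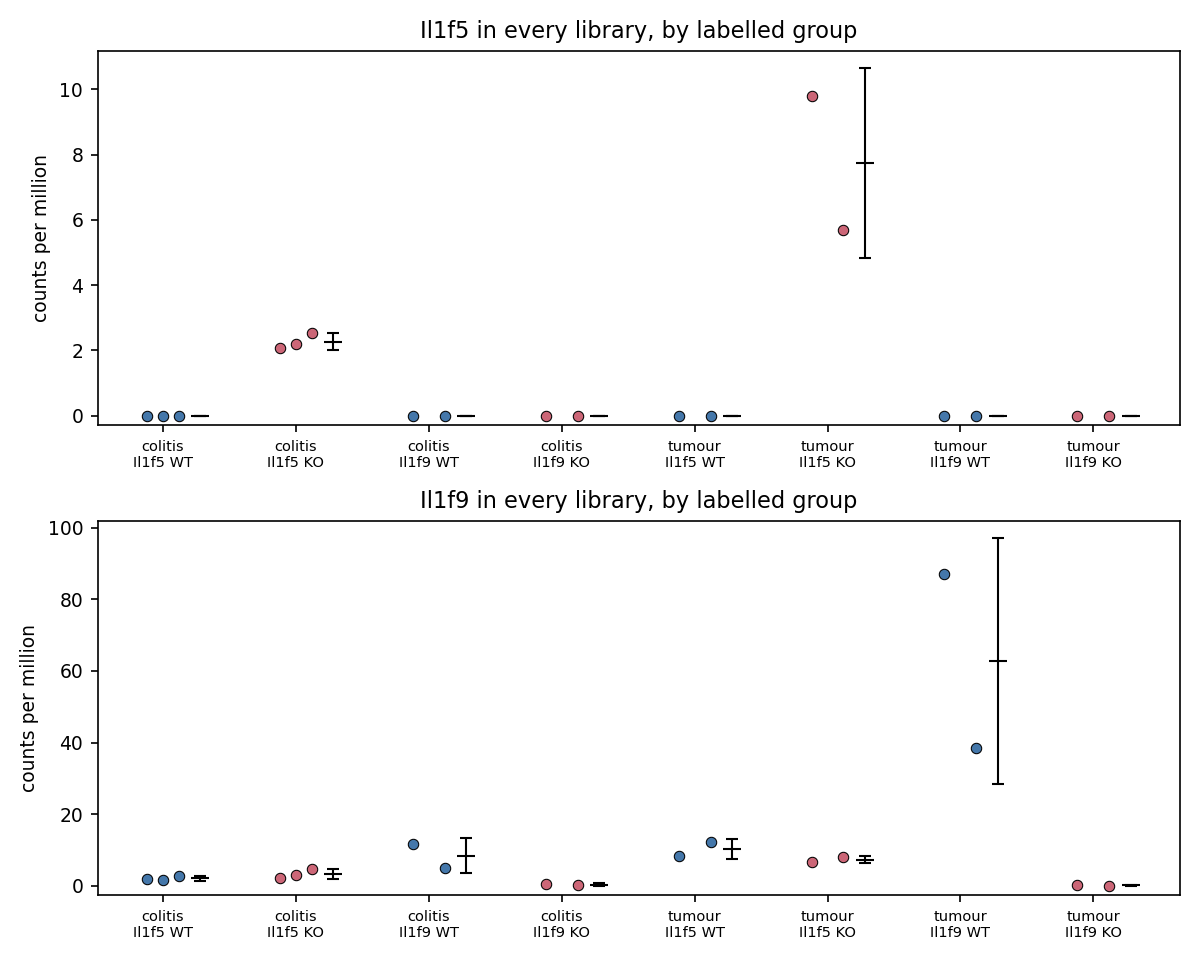
CPM of Il1f5 (top) and Il1f9 (bottom) in every library, by labelled group; points are libraries, and the black dash with bars is the group mean with its SD. The 5 libraries labelled Il1f5 KO are the only ones with Il1f5 counts, and the Il1f9 KO groups average 0.281 and 0.0536 for Il1f9.

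In colitis, libraries labelled Il1f5 KO were compared with WT to ask what loss of the IL-36 receptor antagonist changes. That loss rests on the label, since WT held no Il1f5 reads. Higher in the libraries labelled Il1f5 KO were 25 of 30 collagens and matrix proteins, 12 of 15 smooth muscle, 15 of 16 enteric neuron and glia and 14 of 14 endothelial genes. Lower were 7 of 25 interferon response and 10 of 15 antigen presentation genes, and none of the 21 list calls was kept with an estimated correlation. Ang4, an angiogenin with antimicrobial activity made by gut epithelium (ENSMUSG00000060615, chromosome 14, 51763878 to 51773590), rose, with 735 ± 313 against 32.8 ± 8.64 CPM (n = 3 and 3, log2 fold change 4.42 ± 0.52, adjusted p = 0.00301). Itln1, a lectin that binds microbial sugars (ENSMUSG00000038209, chromosome 1, 171518122 to 171535294), had 34.1 ± 28.1 against 1.07 ± 0.861 (log2 fold change 4.87 ± 0.92, 3.97 without KO 2 to 5.76 without WT 3, adjusted p = 0.0128), and lost its call without WT 2 (adjusted p = 0.0567). Nlrp1b, an inflammasome sensor (ENSMUSG00000070390, chromosome 11, 71153102 to 71230733), fell to 1.42 ± 0.256 against 15.6 ± 1.55 (log2 fold change -3.52 ± 0.19, adjusted p = 8.75e-06), and Slfn8, a member of the Schlafen family (ENSMUSG00000035208, chromosome 11, 83002158 to 83020810), fell to 0.710 ± 0.401 against 13.2 ± 1.87 (log2 fold change -4.29 ± 0.33, adjusted p = 9.65e-05). Grp, which encodes gastrin-releasing peptide, rose by 3.19 ± 0.58 and Inmt, a methyltransferase, by 2.81 ± 0.38 on the log2 scale. Of 18299 genes tested, 2501 were higher and 2015 lower.

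Among 30 collagens and matrix proteins tested, 25 rose, 0 fell and 5 did not pass. For collagens and matrix proteins the median was 0.92, with 27 higher and 0 lower for the list alone, and camera adjusted p = 1.56e-17 (0.374 with estimated correlation). Eln, which encodes elastin (ENSMUSG00000029675, chromosome 5, 134702593 to 134747323), had 109 ± 14.6 against 44.3 ± 4.002 CPM (log2 fold change 1.24 ± 0.15, adjusted p = 0.001002), and Dcn, the collagen-binding proteoglycan decorin (ENSMUSG00000019929, chromosome 10, 97479609 to 97518143), had 449 ± 44.5 against 191 ± 24.3 (log2 fold change 1.17 ± 0.16, adjusted p = 0.00155). Of 22 matrix proteases and inhibitors, 10 rose, 1 fell and 11 did not pass. For matrix proteases and inhibitors the median was 1.12, with 11 higher and 1 lower for the list alone, and camera adjusted p = 3.70e-07 (0.410 with estimated correlation). Timp2, a metalloproteinase inhibitor, rose by 1.36 ± 0.13 and Mmp2, a gelatinase, by 1.21 ± 0.14 on the log2 scale, and the gene that fell was Mmp7, which encodes matrilysin. Of 39 integrin and focal adhesion genes, 17 rose, 5 fell and 17 did not pass. For integrins and focal adhesion the median was 0.31, with 19 higher and 5 lower for the list alone, and camera adjusted p = 4.87e-04 (0.454 with estimated correlation). Those that fell included Itga6, Itgb6, Itga2 and Itga3, genes of epithelial integrins, while Cav1, the main protein of caveolae, rose. With 1 library left out, the adjusted p passed 0.05 for Itga2 (0.0690 without WT 2, 0.0532 without WT 3 and 0.0525 without KO 1) and Itga3 (0.0681 without WT 2, 0.0612 without WT 3 and 0.0659 without KO 2). Of 25 Wnt ligands and regulators, 13 rose, 0 fell and 12 did not pass. For Wnt ligands and regulators the median was 0.70, with 15 higher and 0 lower for the list alone, and camera adjusted p = 1.68e-04 (0.354 with estimated correlation). Rspo1, a secreted amplifier of Wnt signals, rose by 1.34 ± 0.27.

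Marker lists of 10 cell types were called higher in the libraries labelled Il1f5 KO, none with an estimated correlation, and 7 are given here. Whether these, the matrix and the Wnt lists reflect cell make-up of the piece rather than genotype was not tested. All 14 endothelial markers tested rose, including Lyve1 and Vwf. The list median was 0.87, with 14 higher and 0 lower for the list alone, and camera adjusted p = 3.15e-13 (0.353 with estimated correlation). Of 16 enteric neuron and glia markers, 15 rose, 0 fell and 1 did not pass. Their median was 1.42, with 16 higher and 0 lower for the list alone, and camera adjusted p = 3.23e-10 (0.410 with estimated correlation). The marker not called was S100b. Of 15 smooth muscle markers, 12 rose, 0 fell and 3 did not pass. Their median was 0.87, with 13 higher and 0 lower for the list alone, and camera adjusted p = 1.18e-11 (0.374 with estimated correlation). Myl9, a myosin light chain (ENSMUSG00000067818, chromosome 2, 156775420 to 156781658), had 460.1 ± 44.8 against 227 ± 6.21 CPM. Of 15 fibroblast markers, 11 rose, 0 fell and 4 did not pass. Their median was 0.71, with 11 higher and 0 lower for the list alone, and camera adjusted p = 2.05e-07 (0.353 with estimated correlation). Among 11 tuft cell markers, 6 rose, 0 fell and 5 did not pass, including Dclk1 and Alox5. The list median was 1.05, with 8 higher and 0 lower for the list alone, and camera adjusted p = 1.26e-04 (0.410 with estimated correlation). Of 11 adipocyte markers, Cd36 and Cfd rose. For adipocyte markers the median was 0.71, with 1 higher and 0 lower for the list alone, and camera adjusted p = 0.0120 (0.606 with estimated correlation). Of 5 erythrocyte markers, Alas2, Hbb-bt and Hba-a2 rose. For erythrocyte markers the median was 1.75, with 5 higher and 0 lower for the list alone, and camera adjusted p = 0.00576 (0.454 with estimated correlation). Leaving out 1 library raised the adjusted p past 0.05 for Cd36 (0.0706 without WT 1, 0.0659 without WT 2, 0.0615 without KO 1 and 0.0590 without KO 2), Cfd (0.139 without WT 1, 0.141 without WT 2, 0.129 without KO 1, 0.0995 without KO 2 and 0.0531 without KO 3), Alas2 (0.0704 without WT 1, 0.0669 without WT 2 and 0.0733 without KO 2), Hbb-bt (0.0992 without WT 1, 0.0996 without WT 2 and 0.0871 without KO 2) and Hba-a2 (0.0950 without WT 1, 0.09998 without WT 2 and 0.0793 without KO 2).

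Of 25 interferon response genes in the libraries labelled Il1f5 KO, 0 rose, 7 fell and 18 did not pass. For interferon response the median was -0.74, with 0 higher and 10 lower for the list alone, and camera adjusted p = 3.70e-07 (0.454 with estimated correlation). Gbp2, an interferon-induced GTPase (ENSMUSG00000028270, chromosome 3, 142620602 to 142638008), had 48.3 ± 16.6 against 397 ± 105 CPM (log2 fold change -3.10 ± 0.39, adjusted p = 0.00323), and Cxcl10, an interferon-induced chemokine, fell by 3.06 on the log2 scale (-3.87 without KO 3 to -2.70 without KO 2). Of 15 antigen presentation genes, 0 rose, 10 fell and 5 did not pass. For antigen presentation the median was -0.88, with 0 higher and 12 lower for the list alone, and camera adjusted p = 1.13e-06 (0.454 with estimated correlation). Ciita, the transactivator of MHC class II genes, had a log2 fold change of -1.19 ± 0.20. Of 28 proliferation genes, 0 rose, 7 fell and 21 did not pass, and Plk1, a mitotic kinase, was among those that fell. For proliferation the median was -0.79, with 0 higher and 23 lower for the list alone, and camera adjusted p = 8.45e-09 (0.454 with estimated correlation). Neutrophil, T and NK cell, and B and plasma cell lists were each called higher on few members, namely Stfa2l1 and Fpr1 of 20, Cd5 and Ctla4 of 19, and Igha, Mzb1, Igkc and Derl3 of 18. For neutrophil markers the median was 1.15, with 2 higher and 0 lower for the list alone, and camera adjusted p = 0.0237 (0.710 with estimated correlation). For T and NK cell markers the median was 0.69, with 1 higher and 0 lower for the list alone, and camera adjusted p = 0.0358 (0.713 with estimated correlation). For B and plasma cell markers the median was 0.47, with 2 higher and 0 lower for the list alone, and camera adjusted p = 0.0474 (0.710 with estimated correlation). With 1 library left out, the adjusted p passed 0.05 for Stfa2l1 (0.0534 without WT 2), Fpr1 (0.0539 without WT 1, 0.0638 without WT 2 and 0.0554 without KO 2), Ctla4 (0.0945 without WT 1, 0.121 without WT 2, 0.0807 without KO 2 and 0.0673 without KO 3), Mzb1 (0.0571 without WT 1, 0.0918 without WT 2 and 0.0812 without KO 2), Igkc (0.124 without WT 2, 0.110 without WT 3, 0.0509 without KO 1, 0.0835 without KO 2 and 0.0982 without KO 3), Derl3 (0.117 without WT 1, 0.105 without WT 2, 0.121 without WT 3, 0.0983 without KO 1 and 0.160 without KO 2), Il19 (0.0727 without WT 1, 0.0753 without WT 2 and 0.0519 without KO 2), Tnfsf11 (0.0839 without WT 1, 0.0835 without WT 2 and 0.0758 without KO 2) and Ptges (0.0779 without WT 1 and 0.0944 without WT 2). The neutrophil list was no longer called without WT 1, WT 2 or KO 2, the B and plasma cell list without WT 2 or WT 3, and the T and NK cell list without WT 3. Of 5 IL-36 axis genes tested, Il1f5 and Il1rl2, the IL-36 receptor (ENSMUSG00000070942, chromosome 1, 40324610 to 40367562, log2 fold change 1.02 ± 0.21), rose, and the median is the same with Il1f5 at its bound. For IL-36 axis the median was 0.58, with 2 higher and 0 lower for the list alone, and camera adjusted p = 0.0165 (0.354 with estimated correlation). Without Il1f5 and Il1f9, the targeted genes, the list was not called (camera adjusted p = 0.547), nor was it without a filter on low counts (camera adjusted p = 0.0681). Il1f9 was not called (log2 fold change 0.58 ± 0.52, adjusted p = 0.434). Nos2, which makes nitric oxide, and Tnf fell, by 1.86 and 1.21 on the log2 scale, while Il19, Tnfsf11 and Ptges rose, and the inflammatory cytokine list was not called (camera adjusted p = 0.222) but was called higher without a filter on low counts (0.0494), with the replicate number as a block (0.0329), without WT 3 (0.0346) and without KO 1 (0.0207).

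Of 24 absorptive colonocyte markers in the libraries labelled Il1f5 KO, Guca2a rose and Ms4a12, Aqp4, Slc5a8 and Slc26a3 fell. For absorptive colonocyte the median was -0.13, with 1 higher and 4 lower for the list alone, and camera adjusted p = 0.0351 (0.454 with estimated correlation). Aqp4, a water channel, had 111 ± 8.83 against 392 ± 126 CPM (n = 3 and 3, log2 fold change -1.88 ± 0.26). Of 15 enteroendocrine markers, 2 rose, 6 fell and 7 did not pass. For enteroendocrine markers the median was -0.56, with 2 higher and 6 lower for the list alone, and camera adjusted p = 0.00405 (0.410 with estimated correlation). Neurog3, the transcription factor of enteroendocrine progenitors, and Chgb, a granule protein, fell, and Scg2 and Scg5 rose. Of 19 fatty acid oxidation and ketogenesis genes, 5 rose, 1 fell and 13 did not pass, with Acaa2, Angptl4, Pdk4 and Acadm among those that rose and Acadl falling. For fatty acid oxidation and ketogenesis the median was 0.26, with 8 higher and 1 lower for the list alone, and camera adjusted p = 0.00656 (0.463 with estimated correlation). Leaving out KO 3 ended the calls of the IL-36 axis, neutrophil, T and NK cell, B and plasma cell, absorptive, enteroendocrine and erythrocyte lists and left 15 lists called. The absorptive call ended without KO 2 as well. Single genes that lost their calls with 1 library left out were Slc26a3 (0.0625 without WT 1, 0.0661 without WT 2, 0.0520 without KO 1 and 0.0759 without KO 2), Scg5 (0.0639 without WT 1, 0.0656 without WT 3, 0.0578 without KO 1 and 0.0717 without KO 2), Angptl4 (0.0540 without WT 1, 0.08002 without WT 2, 0.0622 without KO 1 and 0.0719 without KO 2), Pdk4 (0.0984 without WT 1, 0.0896 without WT 3, 0.0691 without KO 1 and 0.0607 without KO 2), Acadm (0.112 without WT 1, 0.0904 without WT 2, 0.0815 without WT 3, 0.0539 without KO 1 and 0.130 without KO 2) and Acadl (0.131 without WT 1, 0.143 without WT 2, 0.102 without KO 1 and 0.110 without KO 2), with the adjusted p given. Immediate early and heat shock genes were not called as a list (camera adjusted p = 0.121) but were called lower with the 2 groups alone (0.00108) and without WT 2 (0.0225), and their median of 0.27 differed in sign from their mean of -0.17 and from the direction of the test. The median and mean of epithelial antimicrobial defence genes also differed in sign (-0.09 and 0.48), and the list was not called (camera adjusted p = 0.950).

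Tests of single genes used the edgeR quasi-likelihood F test on all 10 colitis libraries, and 21 of 35 lists were called, 16 higher and 5 lower. Leaving out 1 library moved the counts by more than 1.5 times in 4 cases, to 1158 higher and 826 lower without WT 1, 1108 and 856 without WT 2, 1443 and 1085 without KO 1, and 1387 and 1025 without KO 2. Among the genes named, calls ended without a filter on low counts for Angptl4, Cd36, Cfd, Hba-a2, Hbb-bt, Igha, Igkc, Pdk4, Ptges and Tnfsf11 (adjusted p = 0.0512 to 0.133), with the replicate number as a block for Acadl, Angptl4, Cd36, Cd5, Cfd, Ctla4, Derl3, Igkc, Itga3, Mzb1, Ptges, Scg2, Slc26a3 and Tnfsf11 (adjusted p = 0.0514 to 0.0807) and with the 2 groups alone for Pdk4 and Ptges (adjusted p = 0.0607 to 0.0728).

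In colitis of the Il1f9 line, the comparison asks what loss of IL-36 gamma changes in the inflamed colon. Lower in the Il1f9 KO group were 15 of 20 neutrophil, 16 of 19 macrophage and monocyte, 7 of 15 cytokine, 8 of 26 chemokine and 13 of 22 matrix protease genes. Higher were 14 of 21 xenobiotic metabolism, 5 of 18 goblet cell, 9 of 24 absorptive colonocyte (with 2 lower) and 11 of 15 smooth muscle genes, and none of the 19 list calls was kept with an estimated correlation. Prok2, a chemokine-like peptide of myeloid cells (ENSMUSG00000030069, chromosome 6, 99711299 to 99726392), fell to 0.0286 ± 0.0404 against 6.12 ± 1.60 CPM (n = 2 and 2, adjusted p = 0.00286), with 1 count in the KO group against 236, 234-fold lower with a 95% counting interval of 41.6 to 9287. Marco, a macrophage scavenger receptor (ENSMUSG00000026390, chromosome 1, 120474538 to 120505024), fell to 0.143 ± 0.202 against 13.1 ± 7.01 (log2 fold change -6.43 ± 0.97, adjusted p = 0.00280), and Nlrp1b to 0.370 ± 0.0420 against 18.2 ± 1.59 (log2 fold change -5.50 ± 0.27, adjusted p = 4.05e-06). Lcn2, an iron-scavenging marker of gut inflammation (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), had 10.4 ± 7.42 against 355 ± 18.1 (log2 fold change -5.00 ± 0.95, adjusted p = 0.0143). Lpo, which encodes lactoperoxidase (ENSMUSG00000009356, chromosome 11, 87806428 to 87828289), rose to 207 ± 38.02 against 30.5 ± 7.91 (log2 fold change 2.86 ± 0.28, adjusted p = 5.15e-04). Ang4 rose to 342 ± 207 against 13.3 ± 2.37 (log2 fold change 4.78 ± 0.65, adjusted p = 0.00404). With 1 library left out, the adjusted p passed 0.05 for Lcn2 (0.05995 without WT 2, 0.0532 without KO 1 and 0.0870 without KO 2) and Ang4 (0.0549 without WT 2). The fitted log2 fold changes then ran from -10.92 without KO 1 to -5.36 without KO 2 for Marco, whose KO 2 library is at 0, -6.01 without KO 1 to -4.40 without KO 2 for Lcn2 and 3.98 without KO 2 to 5.29 without KO 1 for Ang4. Of 18299 genes tested, 1754 were higher and 1827 lower.

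Of 19 macrophage and monocyte markers in the Il1f9 KO group, 0 rose, 16 fell and 3 did not pass. Their median was -2.15, with 0 higher and 17 lower for the list alone, and camera adjusted p = 1.04e-32 (0.0952 with estimated correlation). Csf1r, the receptor for the macrophage growth factor CSF1 (ENSMUSG00000024621, chromosome 18, 61105572 to 61132149), had 17.9 ± 2.99 against 86.1 ± 27.2 CPM (log2 fold change -2.15 ± 0.18, adjusted p = 8.54e-05). Lyz2, a lysozyme of myeloid cells (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321), had 103 ± 7.31 against 545 ± 147 (log2 fold change -2.29 ± 0.19, adjusted p = 8.54e-05), and Arg1, which encodes arginase 1, had 2.45 ± 0.650 against 20.6 ± 0.386 (log2 fold change -2.97 ± 0.25). Of 20 neutrophil markers, 0 rose, 15 fell and 5 did not pass. For neutrophil markers the median was -3.70, with 0 higher and 18 lower for the list alone, and camera adjusted p = 3.20e-12 (0.182 with estimated correlation). Fpr1, a formyl peptide receptor (ENSMUSG00000045551, chromosome 17, 17876471 to 17883940), had 0.667 ± 0.187 against 15.5 ± 2.91 (log2 fold change -4.43 ± 0.53, adjusted p = 5.56e-04), and Csf3r, the G-CSF receptor, had 5.42 ± 3.40 against 43.8 ± 0.445 (log2 fold change -2.92 ± 0.39, -3.76 without KO 1 to -2.38 without KO 2). Mmp8, the neutrophil collagenase, had 0.570 ± 0.325 against 62.5 ± 5.69 (log2 fold change -6.70 ± 1.32, -7.40 without KO 1 to -6.18 without KO 2, adjusted p = 0.0161) and lost its call without WT 2, KO 1 or KO 2 (adjusted p = 0.0639, 0.0912 and 0.110). Of 14 endothelial markers, 0 rose, 9 fell and 5 did not pass, and Vwf had 18.2 ± 3.14 against 46.95 ± 14.02. For endothelial markers the median was -0.72, with 0 higher and 10 lower for the list alone, and camera adjusted p = 6.56e-06 (0.262 with estimated correlation).

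Of 15 inflammatory cytokine genes in the Il1f9 KO group, 0 rose, 7 fell and 8 did not pass. For inflammatory cytokines the median was -2.03, with 0 higher and 9 lower for the list alone, and camera adjusted p = 7.24e-09 (0.182 with estimated correlation). Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254) had 27.7 ± 7.66 against 271 ± 116 CPM (n = 2 and 2, log2 fold change -3.20 ± 0.31, -3.62 without WT 2 to -2.60 without WT 1, adjusted p = 5.56e-04), and Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007) had 4.46 ± 0.980 against 19.6 ± 2.38 (log2 fold change -2.03 ± 0.26, adjusted p = 6.79e-04). Of 11 other IL-1 family genes, 0 rose, 6 fell and 5 did not pass. For other IL-1 family the median was -1.18, with 0 higher and 8 lower for the list alone, and camera adjusted p = 7.40e-06 (0.182 with estimated correlation). Of 12 type 3 cytokine genes, Il17a, Il1r1, Il17ra and Ahr fell and 8 did not pass. For type 3 cytokines the median was -0.72, with 0 higher and 6 lower for the list alone, and camera adjusted p = 0.00195 (0.182 with estimated correlation). Il17a, the main cytokine of Th17 cells, had 0.0286 ± 0.0404 against 3.17 ± 0.902, or 1 count against 121. Of 26 chemokines, 0 rose, 8 fell and 18 did not pass. For chemokines the median was -1.41, with 0 higher and 9 lower for the list alone, and camera adjusted p = 8.22e-08 (0.182 with estimated correlation). Cxcl12, a stromal chemokine, had 57.3 ± 1.97 against 149 ± 29.2, and Cxcl13, which attracts B cells, had 7.90 ± 0.107 against 76.6 ± 34.05. Of 5 IL-36 axis genes, Il1f9, Il1rl2 and Il1rap fell. For IL-36 axis the median was -0.73, with 0 higher and 3 lower for the list alone, and camera adjusted p = 0.0391 (0.182 with estimated correlation). Without the targeted genes the IL-36 axis list was not called (camera adjusted p = 0.193). Of 22 matrix proteases and inhibitors, 0 rose, 13 fell and 9 did not pass. Their median was -1.62, with 0 higher and 15 lower for the list alone, and camera adjusted p = 6.87e-11 (0.182 with estimated correlation). Of 30 collagens and matrix proteins, 0 rose, 15 fell and 15 did not pass, and Vcan, a large proteoglycan, had 17.8 ± 1.57 against 59.7 ± 17.4. The list median was -0.66, with 0 higher and 19 lower for the list alone, and camera adjusted p = 2.10e-09 (0.357 with estimated correlation). Of 39 integrin and focal adhesion genes, Cav1 rose, 11 fell and 27 did not pass. For integrins and focal adhesion the median was -0.27, with 1 higher and 13 lower for the list alone, and camera adjusted p = 0.00142 (0.377 with estimated correlation). Of 16 hypoxia and glycolysis genes, Pfkfb3, Hk2, Bnip3, P4ha1 and Ero1l fell. For hypoxia and glycolysis the median was -0.30, with 0 higher and 6 lower for the list alone, and camera adjusted p = 0.00284 (0.327 with estimated correlation). Calls lost with 1 library left out, with the adjusted p, were Il1r1 (0.165 without WT 2, 0.0532 without KO 1 and 0.143 without KO 2), Il17ra (0.0702 without WT 1, 0.0656 without WT 2 and 0.169 without KO 2), Ahr (0.0789 without WT 1, 0.129 without WT 2 and 0.265 without KO 2), Il1rl2 (0.294 without WT 2, 0.161 without KO 1 and 0.118 without KO 2), Il1rap (0.165 without WT 1, 0.0740 without WT 2 and 0.279 without KO 2) and Cav1 (0.148 without WT 1, 0.124 without KO 1 and 0.0892 without KO 2).

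Among 19 epithelial antimicrobial defence genes in the Il1f9 KO group, 4 rose and 7 fell (median -0.57, camera adjusted p = 0.0571), and the list was called lower with the replicate number as a block (0.00796), without WT 2 (4.95e-05) and without KO 1 (0.00344). Of 21 xenobiotic metabolism genes, 14 rose, 0 fell and 7 did not pass. For xenobiotic metabolism the median was 0.82, with 16 higher and 0 lower for the list alone, and camera adjusted p = 1.37e-10 (0.182 with estimated correlation). Nqo1, a quinone reductase (ENSMUSG00000003849, chromosome 8, 107388225 to 107403206), had 62.01 ± 8.86 against 17.6 ± 2.35 CPM (n = 2 and 2, log2 fold change 1.91 ± 0.24, adjusted p = 8.98e-04). Of 18 goblet cell markers, Spink4, Klk1, Zg16, Clca1 and Retnlb rose and 13 did not pass. For goblet cell markers the median was 0.50, with 8 higher and 1 lower for the list alone, and camera adjusted p = 6.09e-05 (0.327 with estimated correlation). Zg16, a lectin of goblet cell granules, had 2078 ± 291 against 1079 ± 90.9 (log2 fold change 1.05 ± 0.17, adjusted p = 0.00196). Of 24 absorptive colonocyte markers, 9 rose, Ms4a12 and Scnn1b fell and 13 did not pass. For absorptive colonocyte the median was 0.50, with 9 higher and 4 lower for the list alone, and camera adjusted p = 0.00142 (0.182 with estimated correlation). Aqp8, a water channel of surface colonocytes (ENSMUSG00000030762, chromosome 7, 123462291 to 123468004), had 431 ± 0.609 against 133 ± 4.78 (log2 fold change 1.81 ± 0.14, adjusted p = 8.54e-05). Of 28 proliferation genes, Pcna and Birc5 rose. For proliferation the median was 0.49, with 0 higher and 0 lower for the list alone, and camera adjusted p = 3.69e-04 (0.672 with estimated correlation). Of 15 smooth muscle markers, 11 rose, 0 fell and 4 did not pass. For smooth muscle markers the median was 1.07, with 12 higher and 0 lower for the list alone, and camera adjusted p = 2.02e-09 (0.261 with estimated correlation). Des, the muscle filament desmin, had 724 ± 58.3 against 300.2 ± 136. Of 12 squamous epithelium markers, Krt17, Krt14, Sprr1a and Krt10 rose, and Krt14 had 2.32 ± 0.189 against 0.364 ± 0.0590. For squamous epithelium markers the median was 0.60, with 4 higher and 0 lower for the list alone, and camera adjusted p = 0.0391 (0.182 with estimated correlation). Of 18 B and plasma cell markers, Igha, Jchain and Mzb1 rose. For B and plasma cell markers the median was 0.65, with 4 higher and 0 lower for the list alone, and camera adjusted p = 6.52e-04 (0.462 with estimated correlation). With 1 library left out, the adjusted p passed 0.05 for Clca1 (0.0542 without WT 2), Retnlb (0.116 without WT 2 and 0.0551 without KO 1), Scnn1b (0.0634 without WT 2 and 0.0596 without KO 2), Pcna (0.186 without WT 2, 0.0551 without KO 1 and 0.171 without KO 2), Birc5 (0.239 without WT 2, 0.159 without KO 1 and 0.119 without KO 2), Sprr1a (0.0742 without WT 2 and 0.0721 without KO 2), Krt10 (0.0976 without WT 1, 0.130 without WT 2, 0.183 without KO 1 and 0.0746 without KO 2), Igha (0.0562 without WT 1, 0.0688 without KO 1 and 0.0770 without KO 2), Jchain (0.0630 without KO 1 and 0.0870 without KO 2) and Mzb1 (0.109 without WT 1, 0.0777 without KO 1 and 0.103 without KO 2). The squamous list was no longer called without WT 2 or KO 1, without a filter on low counts or with the replicate number as a block.

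In this comparison 19 of 35 lists were called, 7 higher and 12 lower. The median and mean of the interferon response list differed in sign (0.05 and -0.29), and the list was not called (camera adjusted p = 0.543) except, as lower, with the replicate number as a block (0.0371). Leaving out WT 2, KO 1 or KO 2 moved the counts to 508, 656 and 661 genes higher and 885, 970 and 833 lower, and leaving out WT 1 ended the calls of the IL-36 axis, B and plasma cell, and hypoxia lists. Calls of named genes ended without a filter on low counts for Birc5, Igha, Il1r1, Jchain, Krt10, Pcna and Retnlb (adjusted p = 0.0549 to 0.125), with the replicate number as a block for Ahr, Cav1, Il1r1, Il1rap, Il1rl2, Krt10 and Pcna (adjusted p = 0.0511 to 0.0920) and with the 2 groups alone for Ahr, Il1rap, Il1rl2 and Krt10 (adjusted p = 0.0883 to 0.110).

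**Figure D2:**
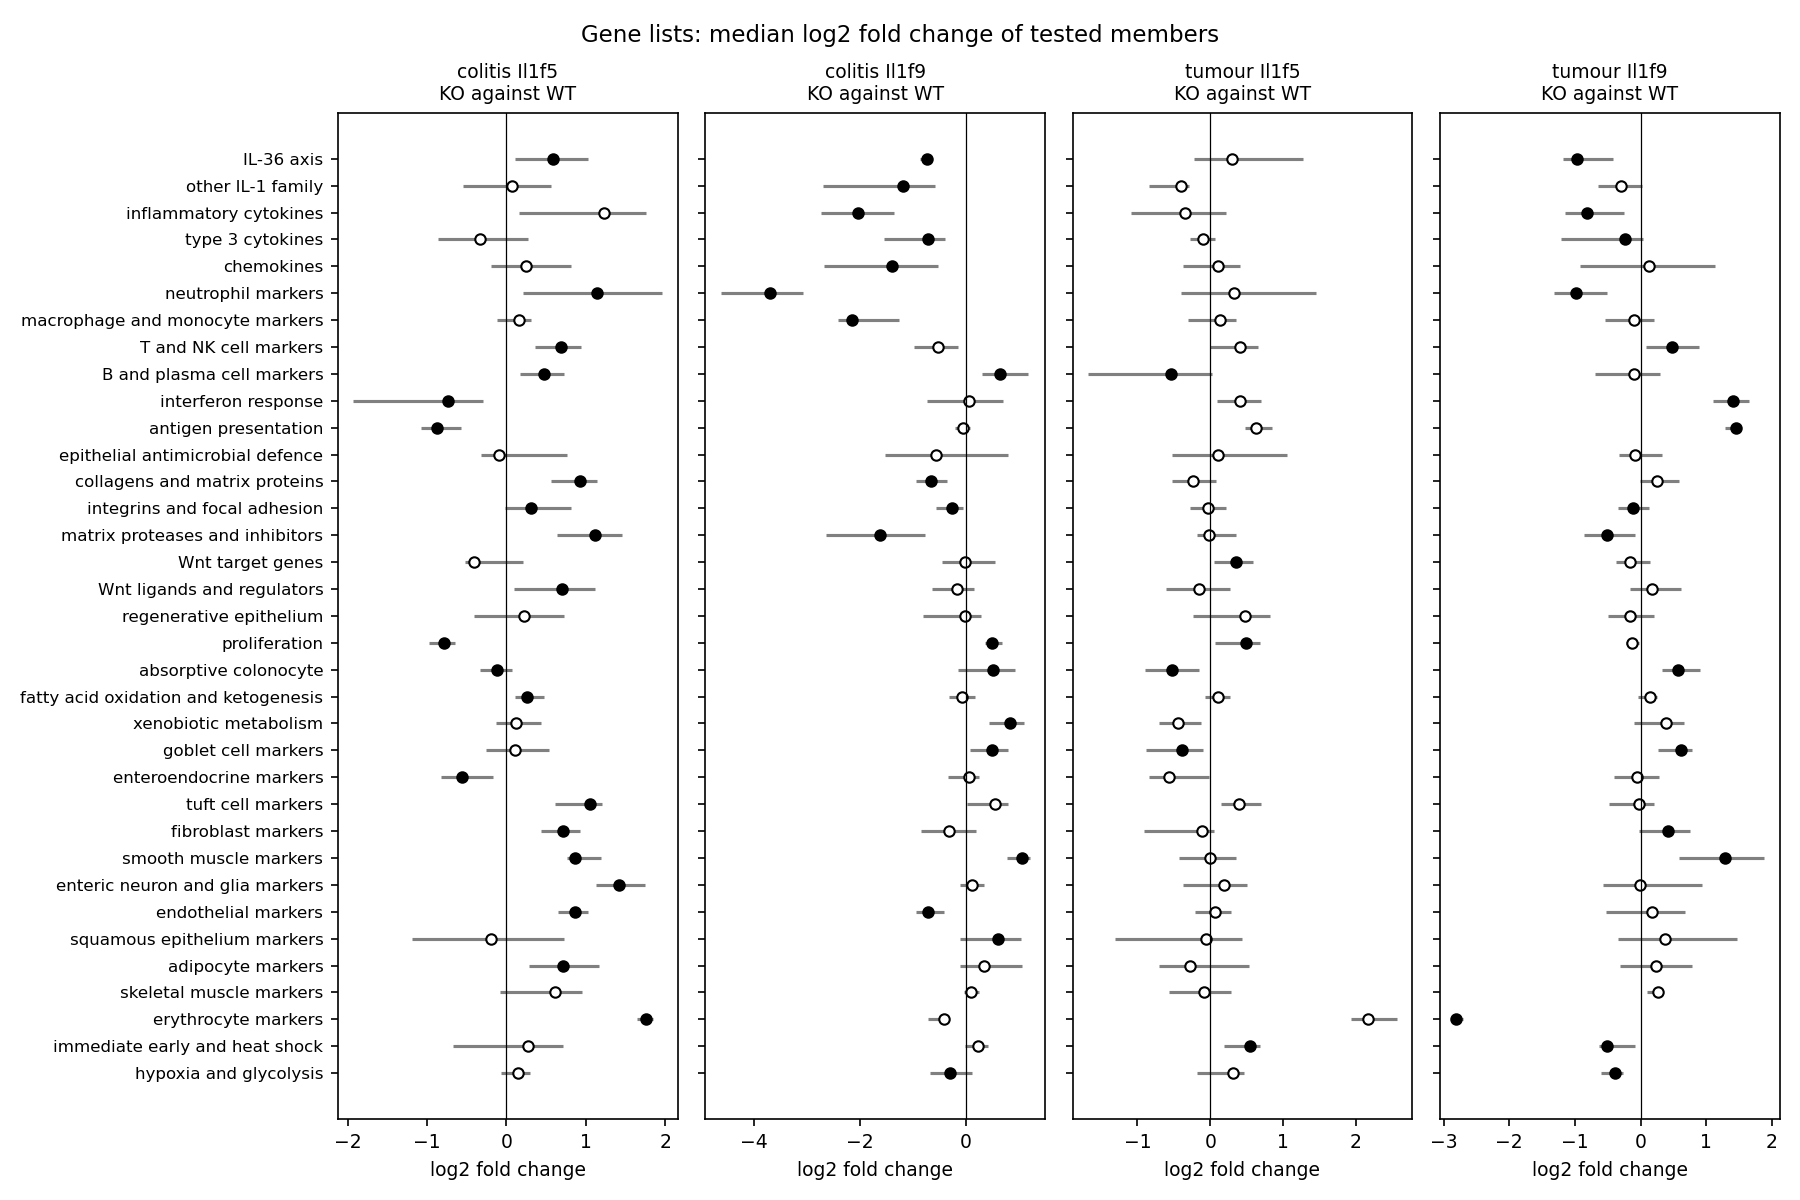
Median log2 fold change, KO over WT, of the tested members of 35 gene lists in the 4 comparisons, with bars from lower to upper quartile; filled points passed the camera test at the preset correlation. Macrophage markers have medians of 0.15 in colitis of libraries labelled Il1f5 KO and -2.15 in colitis of the Il1f9 KO group.

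The Il1f5 and Il1f9 effects in colitis, whose WT groups also differ, were compared directly. The difference passed for 4535 of 18299 genes, 2346 with a higher and 2189 with a lower change in the libraries labelled Il1f5 KO. Without Il1f9 WT 2 it passed for 1961 genes, without Il1f9 KO 2 for 1962 and without Il1f5 WT 2 for 2846. Of the genes called in both comparisons, 169 rose in both, against 239.7 expected if the calls were independent, and 293 fell in both, against 201.2. A further 341 rose in the libraries labelled Il1f5 KO and fell in the Il1f9 KO group, against 249.7 expected, and 235 did the reverse, against 193.1. Ang4 and Retnlb rose in both comparisons, and Nlrp1b, Nos2 and Tnf fell in both. Across genes, which are not independent replicates, the 2 sets of log2 fold changes had Pearson r = -0.0043 and Spearman rho = -0.0786. Exchanging 1 KO with 1 WT library gave r from -0.143 to 0.111 over 9 regroupings of the Il1f5 line. In the Il1f9 line each regrouping has a mirror of the same size, and the absolute r was 0.0689 and 0.342. Without Il1f9 WT 2 the value was r = 0.119.

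In tumours, the comparison of libraries labelled Il1f5 KO with their WT group asks what loss of the antagonist changes in colitis-associated cancer. Again the WT libraries held no Il1f5 reads, so the loss rests on the label. Trp53, which encodes the tumour suppressor p53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873), fell to 16.8 ± 1.90 against 129 ± 12.2 CPM (n = 2 and 2, log2 fold change -2.78 ± 0.15, adjusted p = 2.00e-04). Ephx1, the microsomal epoxide hydrolase (ENSMUSG00000038776, chromosome 1, 180976210 to 181020904), fell to 5.23 ± 0.634 against 23.97 ± 1.72 (log2 fold change -2.03 ± 0.21, adjusted p = 0.0185), and Krt84, a hair-type keratin (ENSMUSG00000044294, chromosome 15, 101525026 to 101532820), rose to 134 ± 39.1 against 33.7 ± 1.24 (log2 fold change 2.16 ± 0.22, adjusted p = 0.0185). The other called genes, named after their values were seen, were the predicted genes Gm14719 (ENSMUSG00000082192), which rose to 32.3 ± 5.03 against 2.63 ± 0.244, and Gm42047 (ENSMUSG00000110631), which fell to 50.7 ± 10.8 against 404 ± 62.7. In all, 2 of 17859 genes rose and 3 fell by the edgeR test, while 4106 had an unadjusted p under 0.05. A DESeq2 Wald test called 705 higher and 574 lower, and edgeR with the 2 groups alone called 450 and 576. Trp53 kept its call in every alternative run for it, and Gm14719 lost its call with the replicate number as a block (adjusted p = 0.0764). The counts without WT 1, WT 2, KO 1 and KO 2 were 0, 0, 4 and 1 higher. With 1 library left out, the adjusted p passed 0.05 for Ephx1 (0.0617 without WT 1, 0.168 without WT 2, 0.209 without KO 1 and 0.0727 without KO 2), Krt84 (0.0818 without WT 1, 0.183 without WT 2 and 0.0585 without KO 2), Gm14719 (0.116 without WT 1, 0.254 without WT 2, 0.169 without KO 1 and 0.0585 without KO 2) and Gm42047 (0.0585 without KO 2).

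No list member passed over all genes in tumours of libraries labelled Il1f5 KO, so list members are given as values. Of 28 proliferation genes, 22 had log2 fold changes above 0. Their median was 0.50, with 14 higher and 3 lower for the list alone, and camera adjusted p = 8.56e-04 (0.919 with estimated correlation). Mcm2 had 130.4 ± 13.8 against 77.7 ± 5.94 CPM (n = 2 and 2, log2 fold change 0.92 ± 0.16, adjusted p = 0.0693). The marker Mki67 was lower (179 ± 11.8 against 265 ± 9.01). Of 22 Wnt target genes, 17 lay above 0, and Ccnd1 (cyclin D1) had 255 ± 45.3 against 149 ± 11.2. The list median was 0.35, with 3 higher and 0 lower for the list alone, and camera adjusted p = 0.0118 (0.919 with estimated correlation). Of 18 goblet cell markers, 14 lay below 0, and Muc2, the gel-forming mucin of the colon, had 712 ± 156 against 1761 ± 660.1 (log2 fold change -1.15 ± 0.26, -1.49 without WT 1 to -0.67 without WT 2). The list median was -0.39, with 0 higher and 7 lower for the list alone, and camera adjusted p = 8.56e-04 (0.919 with estimated correlation). Of 24 absorptive colonocyte markers, 21 lay below 0, and Krt20 had 315 ± 84.7 against 647 ± 118. The list median was -0.52, with 0 higher and 0 lower for the list alone, and camera adjusted p = 0.00711 (0.919 with estimated correlation). Of 15 immediate early and heat shock genes, 14 lay above 0, and Ier2 had 165 ± 2.96 against 105 ± 6.004. The list median was 0.55, with 1 higher and 0 lower for the list alone, and camera adjusted p = 0.0118 (0.919 with estimated correlation). Of 18 B and plasma cell markers, 13 lay below 0, and Ighd had 0.534 ± 0.427 against 3.03 ± 0.570 (log2 fold change -2.37 ± 0.65, -3.44 without KO 2 to -1.77 without KO 1). The list median was -0.53, with 0 higher and 0 lower for the list alone, and camera adjusted p = 0.0256 (0.919 with estimated correlation). In all, 6 of 35 lists were called, 3 in each direction. Leaving out WT 2 ended the Wnt target, absorptive, goblet and immediate early calls and left 3 lists called, leaving out KO 1 ended the proliferation and B cell calls, and leaving out KO 2 ended the immediate early call. The matrix protease list, not called, had a median of -0.02 and a mean of 0.12. All 5 erythrocyte markers lay above 0 (median 2.17, camera adjusted p = 0.0643), and the list was called higher with DESeq2 size factors (0.0478), without a filter on low counts (0.0354), with the 2 groups alone and without KO 2 (0.0185).

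In tumours of the Il1f9 line, the comparison asks what loss of IL-36 gamma changes in colitis-associated cancer. Besides Il1f9, Camk2b, a subunit of a calcium-dependent kinase (ENSMUSG00000057897, chromosome 11, 5969644 to 6066362), fell to 0.211 ± 0.0707 against 8.79 ± 0.649 CPM (n = 2 and 2, log2 fold change -5.36 ± 0.38, adjusted p = 0.00241). Krt84 rose to 101 ± 4.19 against 15.3 ± 4.58 (log2 fold change 2.70 ± 0.23, adjusted p = 0.00664). These 3 were the genes called of 17859 tested by edgeR, while 1553 had an unadjusted p under 0.05 and a DESeq2 Wald test called 82 higher and 82 lower. With the 2 groups alone edgeR called 0 genes, and the adjusted p was 0.0926 for Camk2b and 0.0926 for Krt84. Leaving out KO 2 raised the counts to 79 higher and 18 lower, and leaving out KO 1 raised them to 54 and 25; without WT 1 no gene was higher and 4 were lower, and Krt84 had an adjusted p of 0.0502, and without WT 2 the count lower was 7.

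Apart from Il1f9, no list member passed over all genes in these tumours, and list members are given as values. Of 18 goblet cell markers, all 18 had log2 fold changes above 0. For goblet cell markers the median was 0.62, with 5 higher and 0 lower for the list alone, and camera adjusted p = 3.72e-10 (0.526 with estimated correlation). Muc2 had 186 ± 21.6 against 95.3 ± 3.33 CPM (n = 2 and 2), and Atoh1, the transcription factor of secretory cells, had 8.93 ± 1.25 against 3.81 ± 0.319. Of 24 absorptive colonocyte markers, 21 lay above 0, and Muc3, a membrane mucin, had 157 ± 16.8 against 52.1 ± 7.39. For absorptive colonocyte the median was 0.57, with 1 higher and 0 lower for the list alone, and camera adjusted p = 4.30e-08 (0.526 with estimated correlation). Of 22 neutrophil markers, 21 lay below 0, and Trem1, an amplifying receptor of neutrophils, had 42.7 ± 1.38 against 105 ± 57.03 (log2 fold change -1.33 ± 0.34, -1.83 without WT 2 to -0.58 without WT 1). For neutrophil markers the median was -0.98, with 0 higher and 0 lower for the list alone, and camera adjusted p = 9.06e-09 (0.610 with estimated correlation). Of 16 inflammatory cytokine genes, 14 lay below 0, and Osm, which encodes oncostatin M, had 48.7 ± 1.27 against 115 ± 61.2 (log2 fold change -1.28 ± 0.33, -1.77 without WT 2 to -0.56 without WT 1). For inflammatory cytokines the median was -0.82, with 0 higher and 0 lower for the list alone, and camera adjusted p = 2.21e-04 (0.615 with estimated correlation). The IL-36 axis list holds Il1f9 itself, and 1 of its 6 members fell. For IL-36 axis the median was -0.97, with 0 higher and 3 lower for the list alone, and camera adjusted p = 2.75e-11 (0.0640 with estimated correlation). Without the targeted genes the IL-36 axis list kept its call (camera adjusted p = 2.85e-04, adjusted p = 0.526 with an estimated correlation). Il23a, a subunit of IL-23 (ENSMUSG00000025383, chromosome 10, 128296139 to 128298752), had 14.8 ± 0.921 against 37.1 ± 1.60 (log2 fold change -1.36 ± 0.20, adjusted p = 0.147), and 7 of 10 type 3 cytokine genes lay below 0. For type 3 cytokines the median was -0.24, with 0 higher and 2 lower for the list alone, and camera adjusted p = 0.00805 (0.610 with estimated correlation). Erythrocyte markers had 5 of 5 members below 0. For erythrocyte markers the median was -2.81, with 0 higher and 0 lower for the list alone, and camera adjusted p = 1.81e-06 (0.526 with estimated correlation). Hypoxia and glycolysis genes had 14 of 16 below 0. Their median was -0.39, with 0 higher and 1 lower for the list alone, and camera adjusted p = 7.07e-06 (0.526 with estimated correlation). Matrix proteases and inhibitors had 17 of 22 below 0. Their median was -0.51, with 0 higher and 5 lower for the list alone, and camera adjusted p = 2.93e-06 (0.610 with estimated correlation). Immediate early and heat shock genes had 11 of 15 below 0. Their median was -0.51, with 0 higher and 0 lower for the list alone, and camera adjusted p = 9.55e-05 (0.610 with estimated correlation). Integrin and focal adhesion genes had 25 of 38 below 0. Their median was -0.12, with 0 higher and 3 lower for the list alone, and camera adjusted p = 0.0356 (0.610 with estimated correlation).

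Lists called higher in these Il1f9 KO tumours included interferon response genes, with 25 of 25 above 0. For interferon response the median was 1.41, with 0 higher and 0 lower for the list alone, and camera adjusted p = 3.99e-07 (0.618 with estimated correlation). Antigen presentation genes had 15 of 15 above 0. For antigen presentation the median was 1.45, with 0 higher and 0 lower for the list alone, and camera adjusted p = 7.61e-08 (0.610 with estimated correlation). Library KO 2 stood apart in both, with 14.8 CPM of Ifng, the gene of interferon gamma, 578 of Cxcl9, 769 of Ido1 and 1428 of Cd74. KO 1 had 0.214 of Ifng, 19.4 of Cxcl9, 31.3 of Ido1 and 398 of Cd74. Without KO 2 the interferon list had adjusted p = 0.499 with its direction turned, and the antigen presentation list had adjusted p = 0.535. Smooth muscle markers had 14 of 14 above 0. For smooth muscle markers the median was 1.28, with 0 higher and 0 lower for the list alone, and camera adjusted p = 9.55e-05 (0.618 with estimated correlation). Fibroblast markers had 11 of 15 above 0. For fibroblast markers the median was 0.42, with 0 higher and 0 lower for the list alone, and camera adjusted p = 0.0203 (0.702 with estimated correlation). T and NK cell markers had 15 of 19 above 0 and were called lower without KO 2 (adjusted p = 0.0194). For T and NK cell markers the median was 0.47, with 0 higher and 0 lower for the list alone, and camera adjusted p = 0.0356 (0.844 with estimated correlation). Without KO 2 the smooth muscle, fibroblast, integrin and immediate early calls ended too, and the integrin call ended with the 2 groups alone and with the replicate number as a block. In all, 16 of 35 lists were called, 7 higher and 9 lower, with none called under an estimated correlation. Without WT 1 the inflammatory cytokine, type 3 cytokine, neutrophil, integrin and immediate early calls ended and 12 lists were called, without WT 2 the T and NK cell, interferon and fibroblast calls ended, and without KO 1 the inflammatory cytokine, integrin and matrix protease calls ended.

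**Figure D3:**
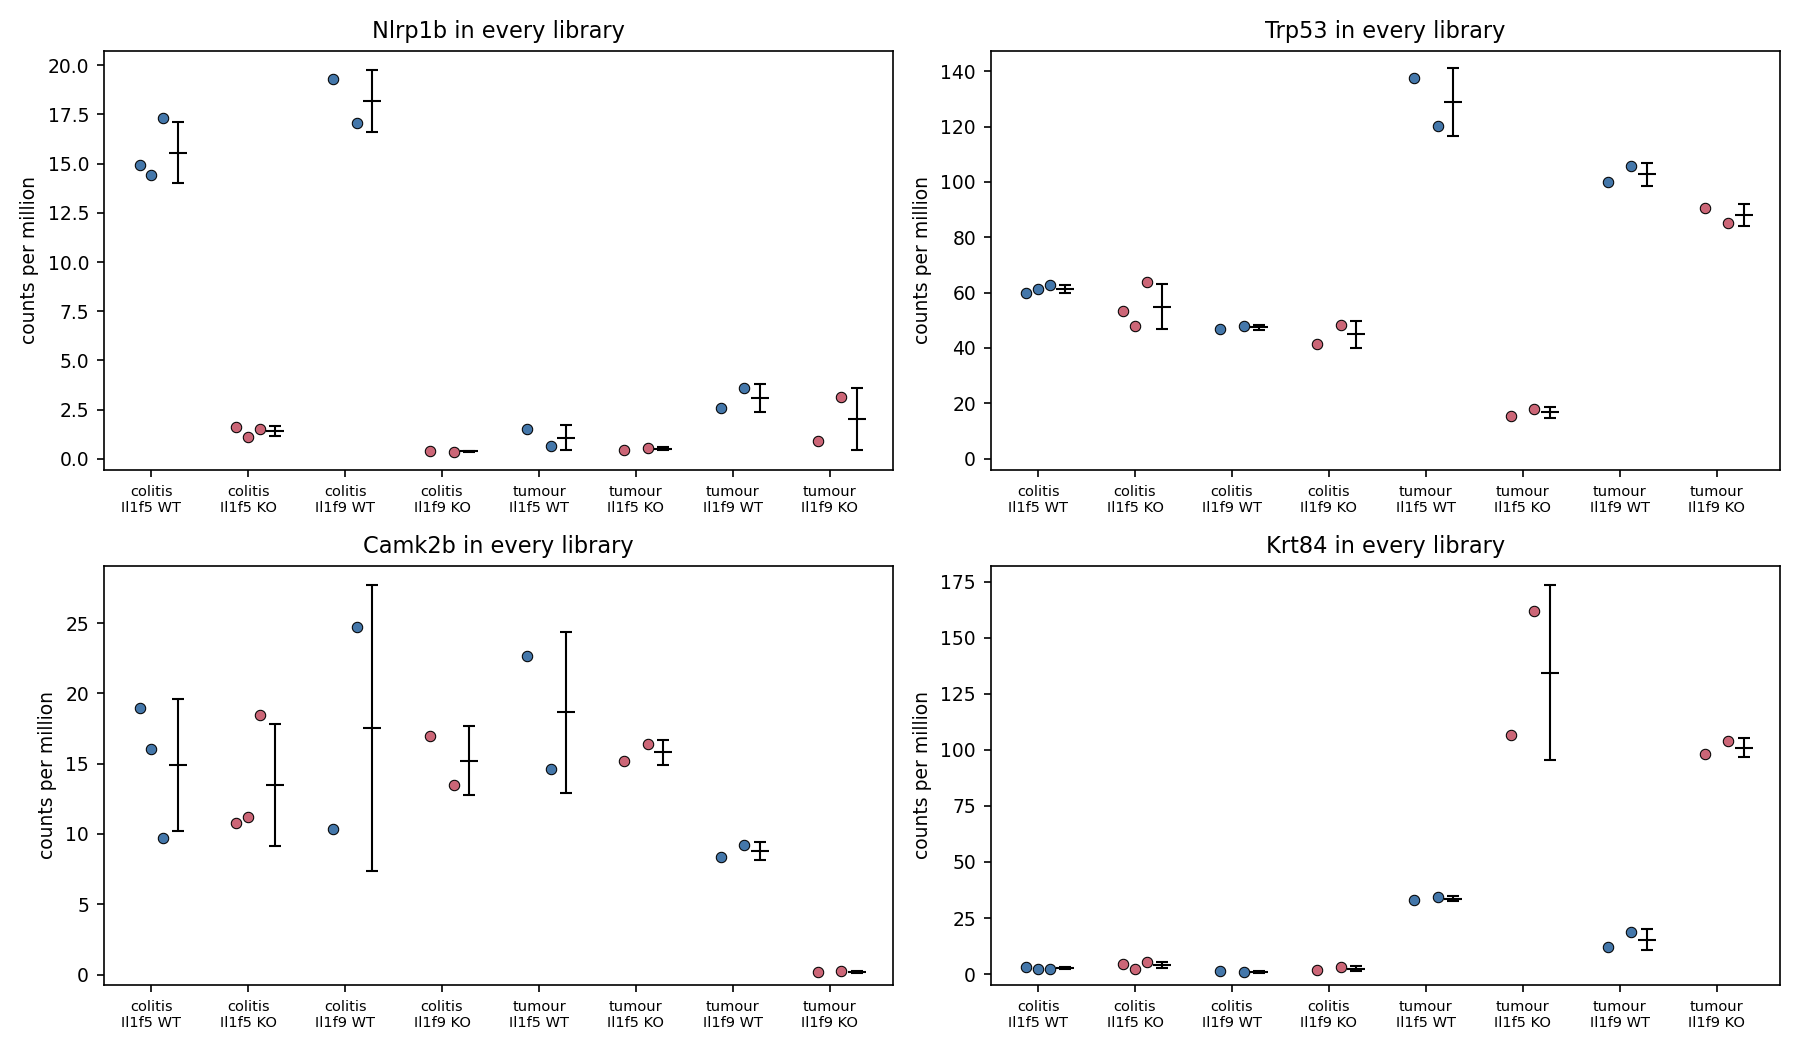
CPM of Nlrp1b, Trp53, Camk2b and Krt84 in every library, by labelled group; points are libraries, and the black dash with bars is the group mean with its SD. Trp53 averages 16.8 in tumours of libraries labelled Il1f5 KO against 129 in their WT group, and Camk2b averages 0.211 in Il1f9 KO tumours against 8.79.

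The tumour effects of the 2 lines differed for 14 of 17859 genes, 6 with a higher and 8 with a lower change in the libraries labelled Il1f5 KO, among them Trp53 and Camk2b. That count was 2 without Il1f5 WT 2, 8 without Il1f5 WT 1, 5 without Il1f5 KO 1, 5 without Il1f5 KO 2 and 8 without Il1f9 WT 1, and it rose to 276 without Il1f9 KO 1 and 319 without Il1f9 KO 2. Krt84 rose in both tumour comparisons. Across genes, which are not independent replicates, tumour effects had Pearson r = -0.0741 and Spearman rho = -0.0731, and the absolute r with 1 KO and 1 WT library exchanged was 0.0334 and 0.0628 in the Il1f5 line and 0.0495 and 0.104 in the Il1f9 line. The tumour effect differed from the colitis effect for 3524 of 19514 genes in libraries labelled Il1f5 KO, 2113 higher and 1411 lower in tumours. Fhl1, a protein of muscle cells, rose in colitis of those libraries (log2 fold change 1.21 ± 0.14) and was not called in tumours (log2 fold change -1.31 ± 0.22, adjusted p = 0.0693), a difference of -2.51 ± 0.27. In the Il1f9 line the effects differed for 482 genes, 322 higher and 160 lower in tumours, and macrophage genes Csf1r and Cd68 were among them with differences of 2.19 and 2.08. The Il1f9 count was 1 when only the 4 groups of that line were fitted, 49 without colitis KO 2, 86 without colitis WT 2, 97 without tumour WT 2, 135 without colitis KO 1, 287 without tumour WT 1, 1025 without tumour KO 1 and 1107 without tumour KO 2. The Il1f5 count was 561 without tumour KO 1, 1407 without tumour WT 1, 2080 without tumour WT 2, 2182 without colitis WT 2 and 2230 without colitis KO 1.

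WT groups were compared between the lines. In colitis 902 of 18299 genes differed, 594 higher and 308 lower in Il1f9 WT than in Il1f5 WT. Arg1 had 20.6 ± 0.386 against 3.24 ± 0.373 CPM (n = 2 and 3, log2 difference 2.61 ± 0.21, adjusted p = 3.03e-04), and Dbp, a clock-controlled transcription factor, had 3.01 ± 0.674 against 31.5 ± 6.94 (log2 difference -3.45 ± 0.27, adjusted p = 3.03e-04). Without Il1f9 WT 2 the count was 118, without Il1f5 WT 1 it was 151 and without Il1f5 WT 2 it was 154. In tumours 5096 of 17859 genes differed, 2999 higher and 2097 lower in Il1f9 WT. Bnip3, a mitophagy receptor induced by hypoxia, had 145 ± 1.80 against 29.2 ± 2.09 (n = 2 and 2, log2 difference 2.73 ± 0.17, adjusted p = 2.27e-04). Leaving out 1 tumour WT library gave 1670 without Il1f5 WT 1, 2070 without Il1f5 WT 2, 1872 without Il1f9 WT 1 and 2891 without Il1f9 WT 2. Line cannot be told apart from table in tumours, nor from collection time in colitis, where clock genes differed.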

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

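The tests of differences between effects were planned, and all tests of explanations were chosen only after the result was seen, except the splits of the colitis Il1f5 libraries. Il1f5 reads were found only in libraries labelled Il1f5 KO, so the loss of Il1f5 rests on the labels. In colitis the effect in libraries labelled Il1f5 KO differed from the Il1f9 effect for 4535 genes by a test of the difference itself. The log2 differences of the 5 genes with the smallest p were 1.94 ± 0.15 for Cxcl12, 3.18 ± 0.25 for Lrrc25, 3.75 ± 0.32 for Cd33, 3.72 ± 0.32 for Arg1 and 3.49 ± 0.30 for Igsf6. In tumours 14 genes differed, among them Trp53 by -2.53 ± 0.20, Camk2b by 5.30 ± 0.46, Ephx1 by -2.47 ± 0.29, Il1f9 by 9.75 ± 0.95 (a fitted value on 2 counts in Il1f9 KO tumours, 8.81 to 13.10 without Il1f9 KO 2 or KO 1) and Mcpt1 by 3.33 ± 0.38. Without Il1f5 WT 2 the adjusted p was 0.150 for Ephx1, 0.144 for Il1f9 and 0.150 for Mcpt1, and it passed 0.05 for at least 1 of the 3 whichever tumour WT library or Il1f5 KO library was left out (0.0538 without Il1f5 WT 1, 0.146 without Il1f5 KO 1, 0.0811 without Il1f5 KO 2, 0.0848 without Il1f9 WT 1 and 0.101 without Il1f9 WT 2, each for Ephx1). With the replicate number as a block it was 0.0707 for Ephx1 and 0.130 for Mcpt1.

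Between tissues, the effect in libraries labelled Il1f5 KO differed for 3524 genes, with log2 differences of -2.55 ± 0.17 for Trp53, -2.51 ± 0.27 for Fhl1, 1.45 ± 0.16 for Snd1, 1.39 ± 0.16 for Stip1 and -2.51 ± 0.29 for Ephx1. The Il1f9 effect differed for 482 genes, with 3.33 ± 0.39 for Igsf6, 2.72 ± 0.32 for Mpeg1, 2.26 ± 0.30 for Myo1f, 2.19 ± 0.29 for Csf1r and 2.08 ± 0.28 for Cd68. These 5 genes had adjusted p from 0.0659 to 0.0751 when only the 4 groups of the line were fitted.

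The colitis comparison of libraries labelled Il1f5 KO called 4516 genes, and 1 of the 10 splits of its 6 libraries, the real one, called as many, with 0 as the highest of the others. For gene lists 2 of 10 splits called as many as the real 21, since the split with WT 1, WT 2 and KO 1 together also called 21. The splits are too few for a share under 0.05.

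The first pattern is that Il1f5 reads appear only in the libraries labelled Il1f5 KO. An exchange of KO and WT labels in that line is argued against, since the 8 libraries of the Il1f9 line, whose Il1f5 gene should be intact, would then hold 779 Il1f5 counts and held 0. Reads of neighbouring genes are argued against by tumour Il1f9 WT 1, which held 1652 Il1f9 counts and 0 of Il1f5. Transcription of what remains of the targeted allele may give these reads and stays open, because gene totals hold no values per exon; the 3 other tested genes within 100 kb had a median log2 fold change of 0.17 in colitis, with 0 called by edgeR. A true difference in genotype was not tested.

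The second pattern is the lower level of 7 genes of chromosome 11 in colitis, namely 3 Nlrp1 genes, 3 Slfn genes and the adjacent 1190001M18Rik, with 7 of 7 called in libraries labelled Il1f5 KO and 5 of 7 in the Il1f9 KO group. With genes at 0 in the KO group put at a floor of 3 counts over the group (1 and 3 of the 7), the median log2 fold changes were -3.52 and -2.86. A fall of the interferon list as a whole is argued against for the Il1f9 line, where its quartiles were -0.73 and 0.70 and its median 0.05. In libraries labelled Il1f5 KO its lower quartile was -1.93. A fall of part of the interferon response stays open in the Il1f9 line. In its colitis libraries Cxcl9 averaged 4.99 CPM in KO against 55.9 in WT, and Gbp2 44.1 against 149. An inherited variant of the KO mice could give the pattern and stays open in both lines, as does genotype itself, which was not tested: in Il1f5 tumours the 4 genes tested (Nlrp1b, Slfn8, Slfn9 and Slfn10-ps) had a median log2 fold change of 0.22, but their WT level there (1.07, 0.422, 20.2 and 0.708 CPM) was under 2 times that left in colitis KO (1.42, 0.710, 13.5 and 0.685), so a loss could hardly show. In Il1f9 tumours their median was -0.48, with 0.911, 1.61, 14.9 and 0.804 CPM in KO 1 and 3.13, 4.85, 29.3 and 4.70 in KO 2, against 2.58, 4.69, 22.7 and 5.48 in WT 1 and 3.58, 3.22, 28.7 and 3.22 in WT 2, and 2 of 7 genes differed between tissues.

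The third pattern is the lower Trp53 level in tumour libraries labelled Il1f5 KO. Loss of a large piece of chromosome 11 is argued against, since 163 other genes within 5 Mb had a median log2 fold change of 0.18, above 99.98% of 10000 random lists. Lower p53 activity may accompany it and stays open, as 33 p53 targets had a median of -0.16, with 5 targets seen first left out (-4.89 for Eda2r, -2.03 for Ephx1, -1.24 for Ccng1, -0.65 for Mdm2 and -0.42 for Cdkn1a), and with camera p = 0.0205 (0.125 with an estimated correlation). Yet the same 33 targets had a lower median of -0.25 in the colitis Il1f9 comparison (camera p = 0.0451, 0.292 with an estimated correlation), where Trp53 was not called (0.03) and Eda2r, Ephx1 and Ccng1 fell too (by 2.21, 1.02 and 0.96). Descent of both libraries from 1 tumour clone could also give it and cannot be told apart, because the Pearson r of 0.96 over 19 autosomes rests on shared WT libraries, and genotype was not tested as the source.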

How the results depend on the processing

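The alternatives were planned except the adjusted p under 0.10 and the IL-36 axis list without the targeted genes, which were chosen after seeing the data, and for each value below the cause was not tested unless stated. With DESeq2 size factors, 21 of 22 summary results stayed within 1.5 times, and the tumour difference between lines moved from 14 to 25 genes. Without a filter on low counts, the WT colitis difference became 1712, tumour Il1f5 1226 higher and 717 lower, tumour Il1f9 462 and 329, the tumour difference between lines 1362, the Il1f9 tissue difference 1823 and the tumour correlation -0.0192. By the DESeq2 Wald test, these were 2077 for WT colitis, 705 and 574 for tumour Il1f5, 82 and 82 for tumour Il1f9, 584 for the tumour difference and 1298 for the Il1f9 tissue difference. An absolute log2 fold change of at least 1, which removes calls by construction, left 1103 higher and 268 lower in colitis Il1f5, 311 and 844 in colitis Il1f9, 2234 for the colitis difference, 339 and 2854 for WT colitis and WT tumours, 1623 for the Il1f5 tissue difference and 6280 for tumour against colitis. An estimated correlation left 0, 0, 0 and 0 lists in the 4 comparisons, with or without the targeted genes in the IL-36 axis list, and 2 in tumour against colitis. Without those genes at the preset correlation the lists called were 20, 18, 6 and 16.

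With the 2 groups compared alone, tumour Il1f5 had 450 genes higher, 576 lower and 12 lists, and tumour Il1f9 had 0 higher and 0 lower by edgeR, where the main test gave 1553 genes with an unadjusted p under 0.05 and DESeq2 called 82 and 82. With the 4 groups of the line alone, the Il1f9 tissue difference was 1. At an adjusted p under 0.10, tumour Il1f5 had 773 higher and 506 lower, and tumour Il1f9 had 2 higher. Over genes called in either comparison, the tumour correlation was 0.235.

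With the replicate number as a block, colitis Il1f5 had 1315 genes higher and 1124 lower, colitis Il1f9 1217 lower, the colitis difference 2810, WT colitis 135, tumour Il1f5 5 higher, the tumour difference 6, WT tumours 1513, and the tissue differences 1646 for Il1f5 and 36 for Il1f9. The labels do not pair KO with WT libraries, and libraries of 1 number were not alike: r between their deviations was -0.0176, -0.174 and -0.202 in colitis Il1f5, -0.138 in colitis Il1f9, -0.0822 in tumour Il1f5 and -0.227 in tumour Il1f9.

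Leaving out 1 library gave 1108 to 3049 higher and 826 to 2537 lower in colitis Il1f5, with 15 to 22 lists, and 508 to 1758 higher and 833 to 1638 lower in colitis Il1f9, with 18 to 22 lists. Tumour Il1f5 had 0 to 4 higher and 2 to 3 lower, with 3 to 8 lists, and tumour Il1f9 0 to 79 higher and 4 to 25 lower, with 12 to 21 lists. The difference between lines was 1961 to 5844 in colitis and 2 to 319 in tumours. The tissue difference was 561 to 3969 for Il1f5 and 49 to 1107 for Il1f9. The WT groups differed for 118 to 1126 genes in colitis and 1670 to 2891 in tumours, and tumour against colitis for 13829 to 14532 genes and 17 to 20 lists. The correlations were -0.0949 to 0.119 in colitis and -0.146 to -0.0199 in tumours.

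Of 4516 genes called in colitis Il1f5, 4485 kept call and direction with DESeq2 size factors, 3880 without the filter and 4056 with the 2 groups alone, but 2383 with the replicate block and 1944 to 4113 with 1 library left out. Of 3581 in colitis Il1f9 the counts were 3535, 3169, 2381, 2332 and 1302 to 2772. Among named genes and comparisons, 738 leave-one-out results kept their side of the threshold, 156 lost and 3 gained a call, and none turned its direction. Depth limits the statements on Il1f5, whose WT libraries hold 0 counts, and 31 and 24% of simulated 2-fold changes were recovered in the tumour designs against 63.2% in colitis Il1f9, which also has groups of 2. The biological coefficient of variation was 0.233 in tumours and 0.158 in colitis.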

Other observations

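Tests here were planned, except those of genes shared by the 4 comparisons, of clock genes and of chromosomes, which were chosen after the result was seen. Tumours against inflamed colon, a comparison in which tissue cannot be told apart from table and preparation, differed for 14162 of 19514 genes, 7121 higher and 7041 lower in tumours. Of 22 Wnt target genes 21 rose (median 3.01, camera adjusted p = 2.38e-31, 0.00639 with an estimated correlation), and of 16 regenerative epithelium genes 13 rose (median 2.05, camera adjusted p = 3.08e-11, 0.00639 with an estimated correlation). Of 20 squamous epithelium markers 17 rose (median 4.68, camera adjusted p = 6.07e-06, 0.315 with an estimated correlation). Of 18 goblet cell markers 17 fell (median -2.36, camera adjusted p = 7.83e-13, 0.111 with an estimated correlation), as did 21 of 24 absorptive colonocyte markers (median -1.72, camera adjusted p = 1.10e-08, 0.111 with an estimated correlation) and 15 of 15 enteroendocrine markers (median -3.26, camera adjusted p = 1.10e-08, 0.0618 with an estimated correlation). All 15 smooth muscle markers fell (median -3.44, camera adjusted p = 2.64e-09, 0.269 with an estimated correlation), with 15 of 16 enteric neuron and glia markers (median -4.77, camera adjusted p = 5.54e-08, 0.269 with an estimated correlation), 10 of 11 adipocyte markers (median -5.36, camera adjusted p = 2.05e-08, 0.184 with an estimated correlation) and 18 of 18 B and plasma cell markers (median -1.68, camera adjusted p = 5.44e-04, 0.508 with an estimated correlation). In all, 17 of 35 lists were called, and 2 with an estimated correlation.

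Genes with an unadjusted p under 0.05 and an absolute log2 fold change of at least 1 in the same direction in all 4 comparisons numbered 2 higher, Gm14719 and Retnlb, against 0.00614 expected if the comparisons were independent, and 3 lower, Gm12891, Ntn5 and Nexmif, against 0.00748. With no minimum fold change they numbered 4 higher against 3.22 expected and 10 lower against 2.58. Gm14719 (chromosome X, 49660960 to 49661299) had log2 fold changes of 2.89, 2.85, 3.79 and 3.02 in colitis Il1f5, colitis Il1f9, tumour Il1f5 and tumour Il1f9, and was named after its values were seen. Of 15 clock genes, 7 were lower and 2 (Arntl and Npas2) higher in colitis Il1f9 WT than in Il1f5 WT. Hspa1a, a heat shock gene, averaged 76.7 CPM in colitis Il1f5 WT and 9.46 in the libraries labelled Il1f5 KO, against 24.7 and 26.9 in Il1f9 WT and KO. In tumours of libraries labelled Il1f5 KO, 690 genes of chromosome 13 had a median log2 fold change of -0.39, below the lowest of 10000 random lists at -0.13, with -0.51 in KO 1 and -0.24 in KO 2. The check list of sex-linked genes had a median of -0.65 in that comparison, with 3 of 4 members lower adjusted over the list alone, and medians of -0.10, -0.16 and 0.01 in colitis Il1f5, colitis Il1f9 and tumour Il1f9.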
